A study of Arabidopsis thaliana with 6 samples.

How the data were processed

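The data were 6 arrays, 2 of wild type, 2 of vip5 and 2 of vip6 plants, with the group and the replicate number taken from the sample titles. The authors deposited 1 table of linear intensity values per probe set, in which no value is negative. The software that made the intensity values is not given in the sources used here, and neither are detection calls or background values. From the values, the authors scaled each array to a common mean with the lowest and highest 2% of probe sets left out, and the trimmed means of the 6 arrays lie within the tolerance of 5% fixed before the data were examined, so the deposited intensities were used with no further normalization.

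Values were tested as log2(intensity + 39.4), where the pseudocount is the median over arrays of the 25th percentile. After 64 control probe sets were left out, a probe set was tested if it lay above the 40th percentile of its array on at least 2 of the 6 arrays, which 14323 of 22746 did. One limma model (limma 3.58.1 in R 4.3.3) with 3 group means was fitted to all 6 arrays, with lmFit and eBayes, 3 residual degrees of freedom before moderation, two-sided tests and Benjamini-Hochberg adjustment over the tested probe sets at 0.05. SDs are those of the deposited intensities, and fold changes and standard errors come from the model. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

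Genes were named through the platform annotation given for the probe sets, updated through gene identifiers to the TAIR10.1 assembly's gene table, which served for names and for neighbouring genes only. Of all probe sets including controls, 13513 name 1 gene, 503 name several and 8794 are not listed; of those with 1 gene, 13436 matched a locus and 77 did not. Probe sets with several genes or none stay unnamed. The rule for named genes, fixed before the data were examined, took the 10 highest and 10 lowest log2 fold changes among probe sets past the threshold that name 1 gene and have both mutant arrays beyond both wild type arrays (all, where fewer passed), and up to 4 members of each of 25 fixed gene lists. No list had over 4 tested members, so all 30 tested members are given. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. A further 26 lists were drawn from gene names in the annotation after the tables were seen and before any test.

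The replicate numbers are shared by the groups, and the labels do not say what they mark. Over the tested probe sets, the differences between numbers 1 and 2 correlated at 0.306 between wild type and vip5, 0.308 between wild type and vip6 and 0.655 between vip5 and vip6. With 2 numbers, this does not establish that the arrays were paired. Because the hybridisation controls also differed by number, values with the number as a block and within each number stand beside the values without it, which remain the main ones as fixed beforehand.

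The model was tested on simulated data for vip5 against wild type, with 200 of 14323 probe sets changed in each of 20 draws. Without the block it found 9.3% of 2-fold and 94.6% of 4-fold changes and made no false call; with the block it found 94.0% and 100% and 8.62% of its calls were false, above the intended 5%. The simulated arrays had an additive effect of the number, as the block assumes, so this comparison favours the block. Alternatives covered the normalization, the pseudocount, the filter on dim probe sets, the variance model, the arrays in the fit, the block, the threshold, the set test and each array left out in turn. The quantile-normalized block, a random block, the block with each array left out and the 26 lists were added after the data were seen. The number of arrays limits the precision, and a table without background values gives no detection limit for dim probe sets.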

Results

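RNA from 3-week-old Arabidopsis thaliana plants was hybridised to oligonucleotide expression arrays, with 2 arrays each for wild type, the vip5 mutant and the vip6 mutant. VIP5 and VIP6 (VERNALIZATION INDEPENDENCE) encode homologues of the yeast proteins Rtf1 and Ctr9, members of the Paf1 complex, which acts with RNA polymerase II during transcription. The labels name plants of one age and give neither the tissue nor whether the arrays of a group came from separate plantings, so p-values measure only the spread between these arrays, which may be technical. Of 22746 probe sets without the controls, 14323 were bright enough to be tested, and 7702 of these name 1 gene in the annotation used. The probe sets of VIP5, of VIP6 and of the FLC and MAF flowering repressors could not be identified, because no probe set is paired with those genes in that annotation. Any of them that were bright enough were tested without a name. The mutant labels were thus not checked against the mutated genes. Fold changes below are on the log2(intensity + pseudocount) scale, which understates the change of dim probe sets, and the number of arrays limits the precision of every value.

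The vip5 arrays were compared with wild type to find the transcripts whose level differs when VIP5 is mutated. QQS (AT3G30720), an orphan gene known for its effect on leaf starch, rose from an intensity of 292 ± 73.0 in wild type to 2555 ± 424 in vip5 (SD, n = 2 each), a log2 fold change of 2.98 with a standard error of 0.23 and a limma adjusted p of 0.00749. PDF1.2b (AT2G26020), a plant defensin gene of the jasmonate and ethylene response, fell from 638 ± 311 to 32.0 ± 21.5 (log2 fold change -3.20, adjusted p = 0.0373). AT2G19970, which encodes a protein of the PR-1-like CAP family, fell from 221 ± 4.81 to 8.90 ± 3.68 (log2 fold change -2.43, adjusted p = 0.00749), and the subtilase gene AT4G21650 fell from 1483 ± 172 to 332 ± 23.4 (log2 fold change -2.03, adjusted p = 0.0197). Higher in vip5 were also AT1G20390, annotated as a pseudogene (log2 fold change 2.05), AT5G56240 (1.63) and AT1G22480, a cupredoxin gene (1.54), each with an adjusted p of 0.0431.

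These 7 genes are all the probe sets that passed the test in vip5, name 1 gene and had both mutant arrays beyond both wild type arrays. In all, 11 of 14323 probe sets passed an adjusted p of 0.05, 5 of them higher and 6 lower in vip5, and the other 4 are not paired with a gene in the annotation used. An unadjusted p below 0.05 was found for 1567 probe sets, where 716 would be expected by chance. Within replicate number 1 and within replicate number 2, QQS differed from wild type by log2 fold changes of 2.58 and 3.37, PDF1.2b by -4.00 and -2.40, AT2G19970 by -2.34 and -2.53, and AT4G21650 by -1.98 and -2.08. AT1G20390 differed by 1.85 and 2.24, AT5G56240 by 1.65 and 1.62, and AT1G22480 by 1.65 and 1.42. With the replicate number as a block, 313 probe sets passed, 140 higher and 173 lower, and the 11 were among them. This fit pools 1 spread over all 3 comparisons, and vip5 and vip6 arrays of a number deviated together more than with wild type. The spread may thus be understated here and in the other block counts against wild type. Both counts, 11 and 313, changed when 1 array was left out, which leaves 1 array in a group and fewer arrays to estimate the spread. Without the block, log2 fold changes then lay between 2.75 and 3.20 for QQS, -3.53 and -2.87 for PDF1.2b, and -2.49 and -2.38 for AT2G19970. PDF1.2b and AT2G19970 were not bright enough to be tested when a wild type array was left out. Their ranges therefore cover only mutant arrays left out and do not show how far they depend on single wild type arrays. The ranges were -2.14 to -1.92 for AT4G21650, 1.755 to 2.34 for AT1G20390, 1.61 to 1.65 for AT5G56240 and 1.43 to 1.65 for AT1G22480. Without the block, the 11 became 0 without wild type replicate 1, wild type replicate 2 or vip5 replicate 2, 1 without vip5 replicate 1, and 18 without either vip6 array. With the block, the 313 became 1282 without wild type replicate 1, 780 without wild type replicate 2, 12 without vip5 replicate 1 and 9 without vip5 replicate 2.

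**Figure D1:**
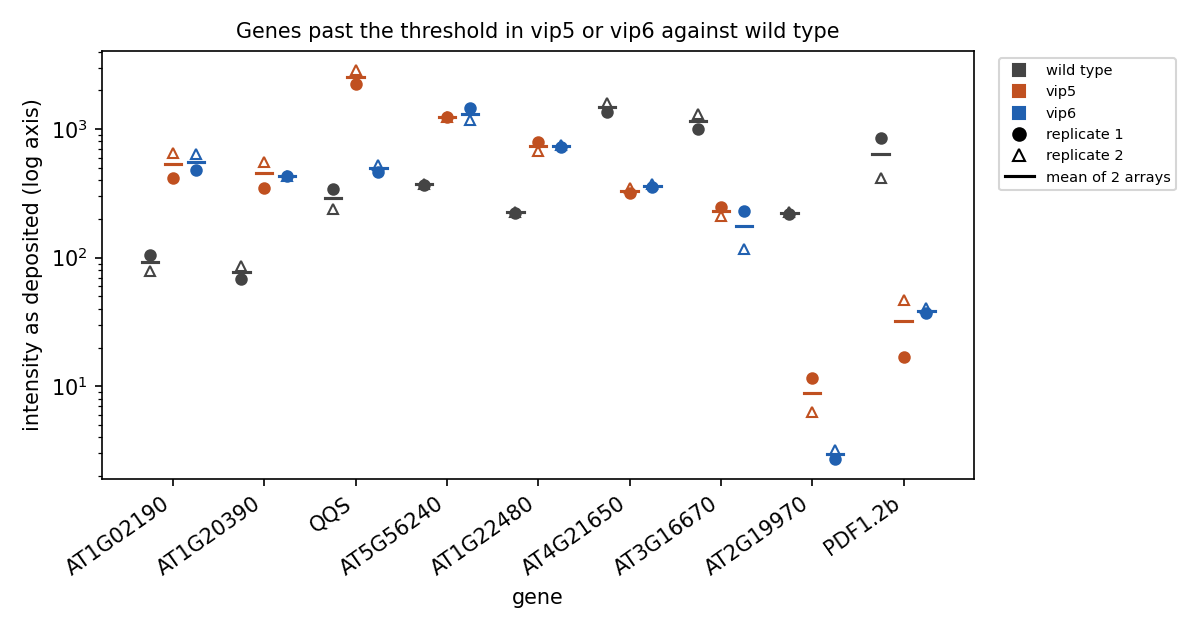
Intensity as deposited (log axis) of the 9 genes that passed the test in vip5 or in vip6 against wild type, with 1 point per array, the replicate number given by the symbol and the mean of the 2 arrays of a group as a bar. QQS lies at 2255 and 2855 on the vip5 arrays and at 466.0 and 525 on the vip6 arrays, against 344 and 241 in wild type.

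The same question was asked of VIP6 with the vip6 arrays. AT1G02190, which encodes a CER1-like protein of the kind that acts in cuticular wax synthesis, rose from 92.3 ± 18.3 in wild type to 559 ± 114 in vip6 (SD, n = 2 each), a log2 fold change of 2.18 with a standard error of 0.26 and a limma adjusted p of 0.0392. PDF1.2b fell from 638 ± 311 to 38.8 ± 2.26 (log2 fold change -3.04, adjusted p = 0.0365). AT2G19970 fell from 221 ± 4.81 to 2.95 ± 0.35 (log2 fold change -2.62, adjusted p = 0.00836), AT3G16670 from 1155 ± 219 to 175 ± 81.1 (log2 fold change -2.52, adjusted p = 0.0365), and AT4G21650 from 1483 ± 172 to 363 ± 13.9 (log2 fold change -1.92, adjusted p = 0.0359). The pseudogene AT1G20390 (log2 fold change 2.02), AT5G56240 (1.72) and the cupredoxin gene AT1G22480 (1.56) were higher, with adjusted p values of 0.0367, 0.0359 and 0.0365. QQS had a log2 fold change of 0.71 in vip6, with an adjusted p of 0.359.

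These 8 genes are all that met the same rule in vip6. In all, 15 of 14323 probe sets passed, 5 higher and 10 lower, of which 6 are not paired with a gene and 1 is paired with several. An unadjusted p below 0.05 was found for 1415 probe sets against 716 expected by chance. Within numbers 1 and 2, AT1G02190 differed from wild type by 1.84 and 2.52, PDF1.2b by -3.55 and -2.52, AT2G19970 by -2.61 and -2.63, AT3G16670 by -1.94 and -3.10, and AT4G21650 by -1.84 and -2.0. AT1G20390 differed by 2.14 and 1.91, AT5G56240 by 1.88 and 1.55, and AT1G22480 by 1.54 and 1.58. With the replicate number as a block, 253 probe sets passed, 103 higher and 150 lower, and the 15 were among them. Without the block, the 15 became 0 without wild type replicate 1, wild type replicate 2, vip6 replicate 1 or vip6 replicate 2, and 5 without either vip5 array. With the block, the 253 became 1155 and 593 without wild type replicate 1 and 2, 81 and 107 without vip5 replicate 1 and 2, and 55 and 48 without vip6 replicate 1 and 2.

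The overlap of the mutants addresses whether VIP5 and VIP6 mutations alter the same transcripts. AT1G20390, AT5G56240 and AT1G22480 were higher, and PDF1.2b, AT2G19970 and AT4G21650 were lower, in both mutants. They belong to 10 probe sets that passed the limma test in both with the same direction, 4 higher and 6 lower, and the other 4 are not paired with a gene. No probe set passed in both with opposite directions. AT1G02190, past the threshold in vip6, had a log2 fold change of 2.1 in vip5 with an adjusted p of 0.0540, and AT3G16670 had -2.14 in vip5 with an adjusted p of 0.0622. With the replicate number as a block both passed in vip5, at 0.00657 and 0.00856.

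Both comparisons use the same 2 wild type arrays, which alone makes fold changes go together. Across the 14323 probe sets, which are not independent replicates, the log2 fold changes of the mutants had a Pearson correlation of 0.836, against 0.50 on average and 0.519 at most in 100 simulations of unchanged mutants with independent array errors. The covariance was 0.103 against a simulated 0.0185, a difference of 0.0842, and 79.2% of probe sets had the same sign against a simulated 66.6%. These simulations leave out that same-numbered vip5 and vip6 arrays deviated together (0.655, against 0.306 and 0.308 with wild type). If errors are shared within a number as the differences between the numbers show, unchanged mutants would have a correlation of 0.727 and a covariance of 0.0421, which leaves a difference of 0.0606, a value computed after the correlations were seen. No simulation with independent errors gave a probe set past the threshold in both without the block, and independent lists of these sizes would share 0.00175 higher and 0.00419 lower probe sets. With the replicate number as a block, 188 probe sets passed in both, 79 higher and 109 lower, against a simulated mean of 0.17 and an overlap of independent lists of 1.01 higher and 1.81 lower. The excess over independent lists may come in part from the shared controls, which the simulations include. The excess over the simulations may come in part from errors shared by same-numbered vip5 and vip6 arrays, which they leave out. The wild type group was not split for these counts, since that would leave 1 array in each part. Without the block, the count of 10 dropped to 1 without vip5 replicate 1 and to 0 without any other single array. With the block, the 188 became 827 and 433 without wild type replicate 1 and 2, 10 and 7 without vip5 replicate 1 and 2, and 51 and 46 without vip6 replicate 1 and 2.

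**Figure D2:**
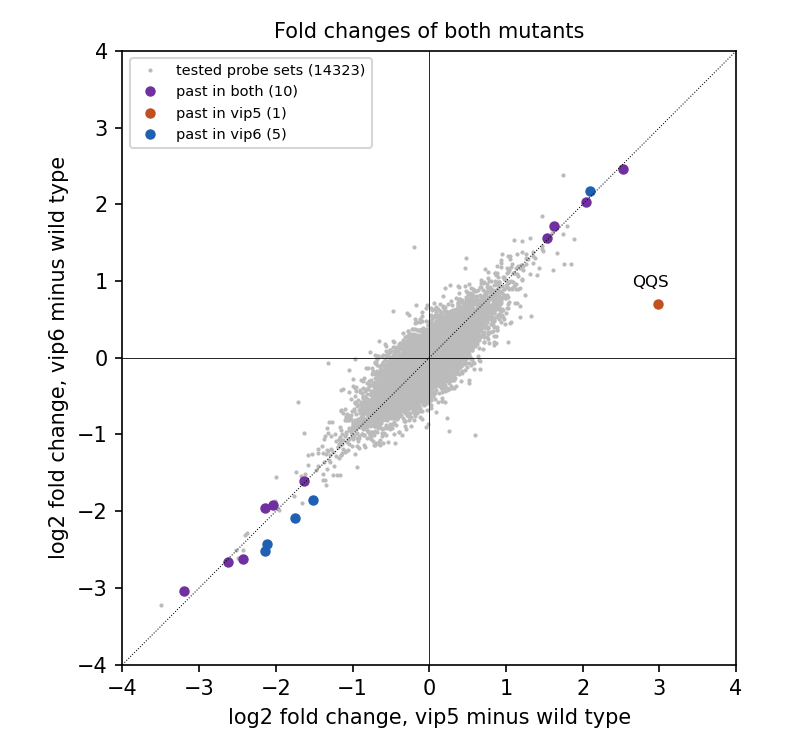
Log2 fold change against wild type in vip5 (x axis) and in vip6 (y axis) for 14323 tested probe sets, with the dotted line marking equal values. The 10 probe sets past the threshold in both mutants lie near that line, and QQS lies apart from it at 2.98 in vip5 and 0.71 in vip6.

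The mutants were compared with each other to find transcripts that depend on which of the genes is mutated. No probe set passed the limma test without the block, and the lowest adjusted p, 0.161, was that of QQS, whose intensity was 2555 ± 424 in vip5 and 496 ± 41.7 in vip6. The log2 difference of QQS, vip6 minus vip5, was -2.27, with a 95% interval of -2.80 to -1.75 that is not adjusted for the number of probe sets. The difference was -2.18 within replicate number 1 and -2.36 within number 2, and QQS was the 1 probe set that passed with the replicate number as a block, with an adjusted p of 0.0434, and did not pass with the block after quantile normalization (adjusted p = 0.119). Of the 6 named genes changed in both mutants, PDF1.2b and AT2G19970 lay near or below the pseudocount in both, where this scale hides a difference between the mutants. The intervals of the difference were from -0.57 to 0.52 for AT1G20390, from -0.35 to 0.52 for AT5G56240, from -0.40 to 0.43 for AT1G22480 and from -0.31 to 0.54 for AT4G21650. An unadjusted p below 0.05 was found for 220 probe sets without the block and for 511 with it, against 716 expected by chance. The 716 assumes independent array errors, here and in the comparisons with wild type. Same-numbered vip5 and vip6 arrays deviated together (0.655, against 0.306 and 0.308 with wild type), so the test is conservative here. The few calls therefore do not show that the mutants are alike.

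Of 25 gene lists fixed before the data were examined, with 282 loci, 38 loci are named by a probe set and 30 were tested, so 4 lists had the 3 members needed for a set test. No list member passed the test over all genes without the block in either mutant. The tested members of the cold and abscisic acid list, COR15A, COR15B, COR47 and LTI30, genes induced by cold and dehydration, all had mean intensities below wild type in both mutants. In vip5 their log2 fold changes were -0.62, -1.53, -0.76 and -0.51, and in vip6 -0.48, -1.26, -0.56 and -0.93. Single arrays moved these values. In vip5, COR15A had -0.32 without vip5 replicate 1, and COR15B had -0.94 and LTI30 -0.28 without vip5 replicate 2. In vip6, COR15A had -0.011 without vip6 replicate 1 and -0.95 without vip6 replicate 2, and COR15B had -0.63 without vip6 replicate 2 and -0.83 without wild type replicate 1. The list passed camera with the preset correlation as lower in vip5 (adjusted p = 0.00176) and in vip6 (adjusted p = 0.0018). It did not pass camera with an estimated correlation (adjusted p = 0.151 in vip5 and adjusted p = 0.151 in vip6). The estimated correlation was -0.0937, below the preset 0.01, so correlation among the members does not account for the loss. With fry, which does not compare the list with other genes, it passed as lower in vip5 (adjusted p = 0.0205) and in vip6 (adjusted p = 0.0147). Adjusted over the list alone, 2 of the 4 members passed as lower in each mutant. With the replicate number as a block, COR15B passed over all genes in vip5 (adjusted p = 0.00746), and COR15B (0.0152) and LTI30 (0.0358) did in vip6. Neither list test nor member test passed for vip6 against vip5, where the adjusted p of the list was 0.861.

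**Figure D3:**
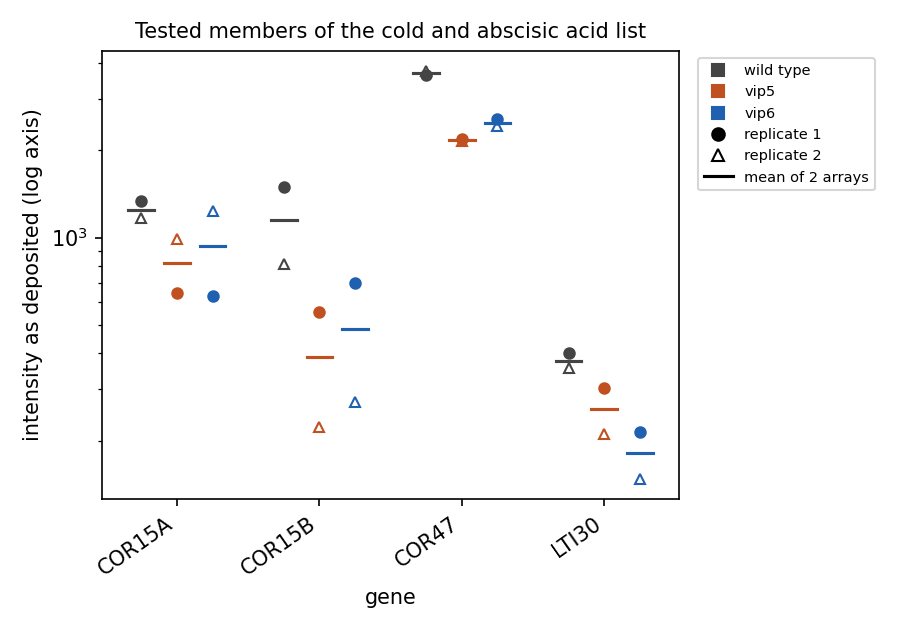
Intensity as deposited (log axis) of COR15A, COR15B, COR47 and LTI30, with 1 point per array, the replicate number given by the symbol and the mean of the 2 arrays of a group as a bar. COR47 lies at 3620 and 3738 in wild type, at 2178 and 2149 in vip5 and at 2554 and 2422 in vip6, and COR15A overlaps between groups, with 1164 on a wild type array and 1237 on a vip6 array.

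The other 3 lists with a set test did not pass. For photosynthesis the adjusted p was 0.486 in vip5 and 0.339 in vip6. Its members LHCB4.1, LHCB4.2 and LHCB4.3, which encode light-harvesting proteins of photosystem II, had log2 fold changes of 0.02, -0.24 and -0.93 in vip5 and 0.08, -0.31 and -1.08 in vip6, and RCA, which encodes Rubisco activase, had 0.31 and 0.03. Adjusted over the list alone, LHCB4.3 passed as lower in both mutants. For flavonoid and anthocyanin synthesis the adjusted p was 0.486 in vip5 and 0.367 in vip6, and the members DFR, UGT75C1, UGT78D2 and UF3GT had log2 fold changes of -0.19, -0.41, 0.11 and -0.09 in vip5 and 0.04, -0.68, 0.17 and -0.38 in vip6. Adjusted over the list alone, none of the 4 passed in vip5 and 1, UGT75C1, did in vip6. For auxin response the adjusted p was 0.486 in vip5 and 0.518 in vip6. Its members IAA29, GH3.3 and WES1 had log2 fold changes of -0.95, 0.91 and -0.23 in vip5 and -0.99, 0.64 and -0.08 in vip6. With 1 array left out, GH3.3 ranged from 0.62 to 1.19 in vip5 and from 0.38 to 0.90 in vip6. IAA29 passed over all genes with the block (adjusted p = 0.0289 in vip5 and 0.0297 in vip6), and adjusted over the list alone 1 member was higher and 1 lower in vip5 and 1 lower in vip6.

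Lists with 1 or 2 tested members were not given a set test. AGL24, a MADS box gene that promotes flowering, was at 274 ± 16.4 in wild type, 102 ± 18.5 in vip5 and 91.8 ± 22 in vip6 (SD, n = 2 each), with log2 fold changes of -1.16 and -1.27 and limma adjusted p values of 0.128 and 0.107. With the block it passed in both, at 0.0257 and 0.0211. The defensin gene PDF1.2 had log2 fold changes of -2.41 and -2.31 (adjusted p = 0.114 and 0.128; 0.0162 and 0.0203 with the block), and BCAT4, of glucosinolate chain elongation, had -1.07 and -1.10 (adjusted p = 0.122 and 0.109; 0.0212 and 0.0203 with the block). PDF1.2 and PDF1.2b are close paralogues, and cross-hybridisation between their probe sets was not checked. GI, a clock and photoperiod gene, was at 624 and 770 in wild type, at 1332 and 474 in vip5 and at 1252 and 545 in vip6 (replicates 1 and 2), so that within number 1 it was higher than wild type in both mutants and within number 2 lower. The flowering repressors SNZ and AGL18 had log2 fold changes of 0.08 and -0.41 in vip5 and -0.05 and -0.18 in vip6, and the autonomous pathway genes FY and LD had 0.40 and -0.13 in vip5 and -0.05 and -0.24 in vip6. The defence genes WRKY53 and SAG101 had -0.18 and 0.36 in vip5 and -0.01 and 0.42 in vip6, STZ of the rapid stress list had 0.78 and 0.54, the replication gene PRL 0.05 and 0.05, and the anther marker AT5G07230 had 0.15 and 0.05. The reference genes AT4G34270 and AT2G28390 had log2 fold changes of -0.06 and 0.22 in vip5 and -0.13 and -0.06 in vip6. None of the genes in these last 3 sentences passed over all genes with or without the block, and 10 of the lists had no tested member. With the block, STZ was higher in vip5 at an unadjusted limma p below 0.05, as its list has 1 tested member and leaves nothing to adjust over. Adjusted over the list alone with the block, 1 of FY and LD passed as lower in vip6 than in vip5. With 1 array left out and no block, STZ ranged from 0.42 to 1.15 in vip5 and from 0.09 to 0.98 in vip6. SAG101 then ranged from 0.085 to 0.635 in vip5 and from 0.15 to 0.69 in vip6.

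The arrays also differed by replicate number in the control transcripts added for hybridisation. The bioB, bioC, bioD and cre controls were 1.4 to 1.96 times as bright on number 2 as on number 1 in wild type, 2.45 to 4.09 times in vip5 and 2.3 to 3.24 times in vip6. The ratio of the 3' to the 5' probe set of actin lay between 1.29 and 1.87 on the 6 arrays, with both ends in wild type, and that of GAPDH between 0.747 and 1.16, again with both ends in wild type.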

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

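Of the tests here, that of the chromosome region was set before its result was seen, and that of single arrays only after the QQS values were seen. QQS stands out because vip6 minus vip5 passed the test in the fit with the replicate number as a block, at -2.27 on the log2 scale with an adjusted p of 0.0434. The call depends on the setting: the adjusted p was 0.161 without the block, 0.119 with the block after quantile normalization, 0.0377 with a random block, and between 0.0579 and 0.78 with the block and any vip5 or vip6 array left out. With the block and a wild type array left out it passed, at 1.76e-05 without replicate 1 and 2.9e-05 without replicate 2. Over the arrays left out in turn without the block, the difference stayed between -2.44 and -2.10 and its adjusted p between 0.399 and 0.9997. A single deviating array is argued against, since the lowest of the 4 differences between a vip5 and a vip6 array was 2.02. QQS was chosen because this same difference passed a test, so the value is partly set by that choice and adds no separate support. A shift of the wider chromosome region is argued against, because the 10 nearest tested genes had a median difference of -0.0454, from -0.392 to 0.17. These neighbours can be far from QQS, so a change of QQS alone, such as a difference between plant lines that is unrelated to VIP5, stays open beside an effect of the vip5 mutation, and neither was tested.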

How the results depend on the processing

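Settings planned before the data were examined are given first. Median scaling, quantile normalization, eBayes with a trend, robust eBayes, a pseudocount at the 50th percentile, a filter at the 60th percentile and a minimum log2 fold change of 1 kept the counts within 1.5 times those reported. Counts are given for vip5, vip6 and both mutants in that order. They were 5, 24 and 4 with the pseudocount at the 10th percentile, and 5 in vip5 and 4 in both with a floor there. Without the filter they were 2, 1 and 1, with only the 2 compared groups in the fit 18, 5 and 4, and at an adjusted p of 0.1 they were 34, 39 and 27. With the replicate block they were 313, 253 and 188, and 1 for vip6 against vip5. The 2 pairs of a comparison do not show that the numbers pair the arrays. Leaving out each array in turn gave 0 to 18 in vip5, 0 to 5 in vip6 and 0 to 1 in both; a lone array was then assumed to vary like the other groups. The cause of these changes was not tested. Lists past the set test went from 1 to 0 in each mutant with an estimated correlation. Which lists passed also changed with arrays left out, which leaves 1 array in a group. The cold list stayed lower in both mutants in each such fit. The flavonoid list turned from lower to higher in both mutants without wild type replicate 1. Photosynthesis turned higher in vip5 without vip5 replicate 1 and in vip6 without vip6 replicate 1. With the other arrays left out, both lists stayed lower than in wild type.

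Settings added after the data were seen were these. The replicate block with quantile normalization gave 266, 175 and 147, with 0 for vip6 against vip5, and a random replicate block 141, 120 and 90, with 1 for vip6 against vip5. The replicate block moved most when arrays were left out as well. Without wild type replicate 1 it gave 1282, 1155, 827 and, for vip6 against vip5, 5. Without wild type replicate 2 it gave 780, 593, 433 and 5. It gave 12, 81 and 10 without vip5 replicate 1, 9, 107 and 7 without vip5 replicate 2, 304, 55 and 51 without vip6 replicate 1, and 288, 48 and 46 without vip6 replicate 2, with 0 for vip6 against vip5 in these.

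The named genes past the threshold kept their direction in every planned setting in which they were tested. Of their 15 calls, 13 were lost without the filter on dim probe sets, 4 to 7 with another pseudocount, 7 with only the compared groups in the fit, 1 with quantile normalization, 2 with the filter at the 60th percentile (AT2G19970 was no longer tested), 9 to 13 with a vip5 or vip6 array left out and all 15 without either wild type array (11 no longer passed and PDF1.2b and AT2G19970 were no longer bright enough to be tested), and none with the replicate block. Genes that were not past it changed sign as follows, and the cause was not tested. With quantile normalization the log2 fold change was -0.10 for LHCB4.1 in vip5, 0.00147 for SNZ in vip6 and 0.0529 for WRKY53 in vip6. WRKY53 in vip6 was also above 0 with median scaling (0.0232), the pseudocount at the 10th percentile (0.0215) and the floor there (0.0336). With arrays left out in turn, the ranges that crossed 0 in vip5 were those of AT1G43590 (-0.66 to 0.28), AT4G34270 (-0.15 to 0.0392), DFR (-0.46 to 0.081), GI (-0.51 to 0.90), LD (-0.29 to 0.0396), LHCB4.1 (-0.44 to 0.47), LHCB4.2 (-0.62 to 0.14), PRL (-0.0877 to 0.18), RCA (-0.15 to 0.77), SNZ (-0.31 to 0.45), UF3GT (-0.47 to 0.29), UGT78D2 (-0.0805 to 0.31) and WRKY53 (-0.86 to 0.50). In vip6 they were those of AGL18 (-0.49 to 0.13), AT2G28390 (-0.23 to 0.12), AT5G07230 (-0.13 to 0.23), DFR (-0.23 to 0.31), FY (-0.16 to 0.064), GI (-0.33 to 0.82), LHCB4.1 (-0.33 to 0.49), LHCB4.2 (-0.63 to 0.00237), RCA (-0.42 to 0.48), SNZ (-0.21 to 0.11), UF3GT (-0.76 to 0.00336), UGT78D2 (-0.0294 to 0.36), WES1 (-0.23 to 0.069) and WRKY53 (-0.69 to 0.66). Under the added settings single genes were counted only: 3 of 218 values changed sign with the quantile-normalized or random block and 39 of 630 with the block and an array left out, none of them past the threshold there or as reported. Background values were not used here, so no limit from signal over background is given.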

Other observations

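Genes that passed only with the replicate number as a block were chosen by the fixed rule applied to that alternative, after the counts of both fits were known. AT3G16530, which encodes a legume-type lectin, had log2 fold changes of -3.49 in vip5 and -3.22 in vip6 (limma adjusted p = 0.00657 and 0.0081 with the block, 0.0552 and 0.0681 without it), and JAL23, of the jacalin-type lectins, had -2.01 and -1.87 (0.0116 and 0.0148 with the block). AT1G69480, of the PHO1 type, had -2.52 and -2.51, AT1G19960 -2.49 and -2.61, and AT1G13650 -1.76 and -1.80. Above wild type in both mutants were the Bet v 1-like genes AT4G23680 (1.55 and 1.52) and AT1G70880 (1.46 and 1.85), the ERD6-like sugar transporter gene AT3G05400 (1.47 and 1.41), AT1G43910 (1.35 and 1.33), AT5G17850 (1.25 and 1.3) and AT5G27410 (1.21 and 1.38). The transcription factor gene bZIP44 had 0.95 and 1.35, and the beta-glucosidase gene BGLU28 and the asparaginase gene ASPGB1 passed in vip5 with the block (1.89 and 1.75) and not in vip6 (1.55 and 1.23, adjusted p = 0.0881 and 0.103), a difference that did not pass when tested. Single arrays moved some of these values in the fit without the block. AT3G16530 ranged from -4.275 to -2.70 in vip5 and from -3.347 to -3.095 in vip6 with 1 array left out. ASPGB1 had 0.96 in vip5 without vip5 replicate 2, and in vip6 2.08 without vip6 replicate 1 and 0.37 without vip6 replicate 2. AT1G13650 had -1.15 in vip5 without vip5 replicate 1 and -0.99 in vip6 without vip6 replicate 1, and AT1G19960 had -1.65 in vip6 without vip6 replicate 2. AT1G43590, a pseudogene, passed in vip6 with the block (1.45) and had -0.20 in vip5, and the difference of 1.64 between the mutants did not pass (adjusted p = 0.156 with the block and 1 without it).

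None of the 26 lists drawn from gene names passed after adjustment, with or without the block. The lowest adjusted p was 0.098 in vip5 without the block, shared by the cytochromes P450, of which 11 of 13 tested members lay below wild type, and the AGAMOUS-like MADS box genes, with 5 of 7 below. In vip6 the lowest was 0.155, and 6 lists had an unadjusted p below 0.05, among them the SWEET sugar transporters with 7 of 10 members above wild type and the expansins and xyloglucan endotransglucosylases with 11 of 14 below.

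The next tests concern arrays with the same replicate number, which deviated together; they were set before their results were seen, but after the correlations of 0.306, 0.308 and 0.655 were known. Different intensity distributions are argued against, since quantile normalization left the lowest of the 3 correlations at 0.291. Shared background in dim probe sets is argued against, since the lowest correlation in the brighter 7161 tested probe sets was 0.335. A day of planting, harvest or hybridisation shared by the arrays of a number stays open, and no label gives one.

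That the vip5 and vip6 fold changes go together was tested only after the values were seen. Independent errors of the shared wild type arrays alone are argued against, since fold changes that share no array and no number correlated at 0.331 and 0.344 across probe sets. In 100 simulations without effects and with independent array errors, such correlations reached at most 0.0355. A deviation common to both wild type arrays would also raise them and was not separated. The earlier covariance difference of 0.0606 rests on the same fold changes across numbers, so it is not separate evidence. Mutant plants grown or handled apart from wild type cannot be told apart from an effect of both mutations, because every mutant array would share it, and the number differences of the mutants correlated at 0.655 with each other against 0.306 and 0.308 with wild type. A shared effect of the mutations is a hypothesis that these 6 arrays leave open.

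As a hypothesis set before its test, genes changed in both mutants with the block might lie next to each other or on 1 chromosome. Of 7534 placed genes, 95 changed in both, and 3 pairs of adjacent tested genes changed the same way, against 0.615 on average in 10000 random placements (one-sided permutation p = 0.0253, 0.0506 adjusted over 2 tests). The pairs were AT1G21520 with AT1G21540, AT1G31690 with AT1G31710, and AT1G62480 with AT1G62500, and cross-hybridisation between neighbours of similar sequence was not checked. Chromosome 1 held 36 of the 95, 1.82% of its tested genes, against 0.832% to 1.46% on the others (permutation p = 0.0549, the same after adjustment). The criterion set beforehand was an unadjusted p below 0.05, which the adjacent pairs met and the chromosomes did not. The adjustment over both tests was brought in after the p-values were seen, and the adjacent pairs are left open because they did not pass with it. A p of at least 0.05 had been set beforehand as a result against either hypothesis, and the chromosomes met that. This bound was set aside after the p-values were seen, as a p that misses a threshold does not show equal shares and chromosome 1 held the highest share, so a concentration there is neither shown nor excluded.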
